A study of Mus musculus with 8 samples.

How the data were processed

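The series profiled gene expression in the 4T1.2 model, a mouse mammary carcinoma line that spreads spontaneously from the mammary gland to bone after transplantation into syngeneic BALB/c mice. Per the labels, tumour epithelial cells were isolated from primary tumours in the mammary gland and from matched spine metastases, total RNA was extracted on columns with DNase digestion, and RNA quality was monitored on a capillary electrophoresis instrument. The sort or gate used for the isolation was not given in the sources used here. Per the labels' protocols, RNA was labelled with biotin in 2 rounds of amplification, a scheme used for small amounts of RNA. There were 8 arrays in 2 groups, 4 of primary tumour and 4 of bone metastasis, and per the series' design text both tumours of a replicate number came from the same mouse, so that the 4 numbers stand for 4 mice.

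The deposited values were log2 signals, 1 per probe set and array, which the authors made with RMA per the submitters' processing notes. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. Its software version, the set of arrays normalized together and any later adjustment were not given in the sources used here. The deposited log2 medians over probe sets ran from 5.15 to 5.42 on the 8 arrays rather than being identical, and the standard deviation over probe sets was 2.24 ± 0.02 (SD, n = 4) in the primary group and 2.08 ± 0.14 (SD, n = 4) in the metastasis group. Scanner files were not used here, so background, probe-level and present or absent calls were not recomputed. No column of per-sample values was left unused and no value was missing.

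Of 45101 probe sets, 64 were control probe sets, 34945 had 1 gene symbol in the platform annotation, 932 had several and 9160 had none listed there. Probe sets with several symbols or none were left out of all tests. The identifiers of 34741 of the named probe sets were found in the mouse gene table of assembly GRCm38.p6, and this table updated 0 symbols. The 18193 genes with a probe set of their own were tested, and 9010 of them had more than 1. For each gene the probe set with the highest mean over the 8 arrays was used. Probe sets of a gene can disagree, since they lie at different places in its transcripts: 280 genes had both a probe set with a significant rise and one with a significant fall, and this held for 201 of the 2432 called genes with more than 1 probe set. Of the genes named by the rule below, another probe set lay on the other side of 0 for Vim (0.07), Cxcl11 (0.20), Csn3 (0.19), Aurka (0.08), Tgfbr1 (0.04), Asns (-0.02), Atf4 (-0.68), Cox7a2 (-0.13), Ndufv1 (-1.30) and Uqcrc2 (-0.79). Of 282 list memberships not called, 52 had another probe set with a call, 13 higher, 36 lower and 3 both.

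Bone metastasis was compared with primary tumour by limma (lmFit and eBayes, version 3.58.1, R 4.3.3) on the log2 values as deposited, without a filter on dim genes and without a block, with Benjamini-Hochberg adjustment over the 18193 genes and a threshold of 0.05 on the adjusted p. Folds are differences of log2 means, metastasis minus primary, with their standard errors (SE). The test was two-sided. A second count asked also for a 2-fold difference. A fold is not exact where the dimmer group lies under the array median (5.16 in primary tumours, 5.31 in metastases), which held for 17 rises named by the rule (Nefl, Ebf1, Fmod, Vpreb1, Prg4, Pirt, Mapk10, Elavl2, Tjp3, Ibsp, Col2a1, Slc4a1, Klrd1, Pvalb, Tnnt3, Nefm and Snap25) and 8 falls (Adamdec1, Trim30d, Ddx60, Krt19, Foxc2, Csn2, Bub1 and Cxcl5). The number of arrays limits the precision, and the SE of a gene's fold had a median of 0.23 over all genes. Gene lists, 29 in all, were compared with the other genes by limma's camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation was run as an alternative. Fry was run too, but it tests a list's genes against no change on balance and not against the other genes, so its values do not bear on camera's question. Each list's calls were counted over all genes tested and adjusted over the list alone, and its median was set against 10000 random lists matched on mean expression in 50 bins. Control measures were compared by exact permutation tests of the 8 arrays, two-sided, with Benjamini-Hochberg adjustment over 13 controls. These tests took the arrays as unpaired, and 0.0286 was the smallest p they allow. Only 8 of the 35 splits of the arrays part both arrays of every mouse, too few for a paired p under 0.05. Intervals of list medians were 95% bootstrap intervals over genes from 10000 resamples, which leave out the spread between arrays. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.

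The genes named were taken by a rule set before the data were examined: the 10 largest rises and 10 largest falls among genes past the threshold with the same direction in all 4 mice (leaving out immunoglobulin and T cell receptor segments and unnamed transcripts, of which 0 and 0 were passed over), the 4 members with the smallest adjusted p of each list with at least 3 members called, the 2 such members of each other list, and Irf7. The tests, the 29 lists and most alternatives were also set before the data were examined. Irf7, both interferon lists and the list of major histocompatibility complex (MHC) class I genes were set with knowledge that the study had followed Irf7 and its targets in these samples. Genes and alternatives chosen later are marked where they appear.

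The replicate numbers pair the arrays by design, since both tumours of a number came from 1 mouse. Over all genes, the deviations of same-numbered arrays from their group means correlated at 0.17, 0.01, 0.02 and -0.11 for replicates 1 to 4, and the consensus correlation within mice was 0.0173. The fit with the mouse as a block called 3284 genes, of which 3114 were among the 3975 called without it. Blocked values are given beside a result only where they change its call.

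Simulated arrays, 4 against 4, had the real genes' means and, in both groups alike, each gene's spread pooled over the groups. In each of 20 runs 200 of 18193 genes were changed. The fit recovered 35.4% of genes changed by 1 on the log2 scale and 76.6% of those changed by 2, and 6.11% of its calls were false. Real metastasis arrays correlated less with each other than primary arrays did (0.903 to 0.957 against 0.981 to 0.993), and 3975 real genes were called. These rates may therefore not hold for the real arrays. A list lowered in the simulation was called in 20 of 20 runs and an unchanged list in 0 of 20. The simulated genes were drawn independently, whereas the estimated correlation within real lists reached 0.76. The simulation therefore cannot show how often camera calls unchanged lists of correlated genes. On the real arrays, other splits of the 8 arrays called up to 17 lists while calling 0 genes.

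Alternative settings chosen before the data were examined were the mouse as a fixed or random block, filters on dim genes at the median and the 75th percentile, quantile normalization, scaling to the 75th percentile, cyclic loess, a trended and robust variance, array weights, the mean or the most variable of a gene's probe sets, every probe set as its own test, and leaving out each array and each mouse in turn. Camera was not run with the random block, and it took the trended but not the robust variance. Alternatives chosen after seeing the data were leaving out bone metastasis replicates 1 and 3 together, each array's actin 3' minus 5' control difference as a covariate, the probe set brightest in metastasis, and replicates 1 and 2 against replicates 3 and 4 as a block.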

Results

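Gene expression was measured on 8 one-colour arrays, 4 of primary 4T1.2 mammary tumours and 4 of spine metastases from the same 4 mice. The comparison asked which transcripts differ between tumour cells growing in bone and their matched primary tumour. Arrays carry no read depth, and their number sets the precision.

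Bone metastasis differed from primary tumour in a large part of the transcriptome, in both directions. With its preset correlation camera called interferon response, MHC class I, macrophage, inflammatory and glycolysis genes lower, and granulocyte, B lineage, nerve and cartilage genes higher. No call of any of the 29 lists held with an estimated correlation. With the actin control difference as a covariate, an alternative chosen after seeing the data, MHC class I genes were called higher and the directions of the inflammatory and cartilage lists turned. This covariate is nearly tied to the group and left 0 genes past the threshold by limma, so these turns are extrapolations. Irf7, the transcription factor that drives type I interferon responses, had a log2 signal of 9.27 ± 0.33 (SD, n = 4) in primary tumours and 7.23 ± 0.34 (SD, n = 4) in metastases, and it was lower in all 4 mice. Its log2 fold was -2.04 with an SE of 0.23, a 4.12-fold fall (limma adjusted p = 0.00114). With the actin covariate the fold of Irf7 was -2.48 with an SE of 0.87 and was no longer past the threshold (limma adjusted p = 0.355).

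Of 18193 genes, 3975 passed the threshold by limma with Benjamini-Hochberg adjustment, 1768 higher and 2207 lower in bone metastasis, so that 55.5% of the calls were lower. Of the calls, 3915 went the same way in all 4 mice, which follows largely from their being called on these same arrays. Over all genes 7979 (43.9%) did so, against 12.5% if directions were random in each mouse. That share allows for no array-wide shift between the groups. The array medians did part the groups (5.15 to 5.17 on primary arrays, 5.23 to 5.42 on metastasis arrays). The excess therefore cannot tell tissue from array effects. At least a 2-fold difference was found in 2897 genes, 1099 higher and 1798 lower. The split between rises and falls depended on the scaling: it was 2453 higher and 1962 lower after scaling to the 75th percentile and 968 higher and 1951 lower after the stricter filter on dim genes. After quantile normalization 49.2% of calls were lower. The scaling to the 75th percentile moved the median fold of all genes by 0.20, from 0.09 to 0.30, so directions of small folds rest on the scaling. The background of a list median depended on brightness, so the median of 0.09 does not serve for every list. Random lists matched on mean expression had medians from -0.64 (for oxidative phosphorylation) to 0.22 (for muscle). Of 10000 such lists, 3421 were as low as TGF-beta genes, and 653 and 1975 as high as muscle and nerve genes. These called lists therefore do not stand out by their medians. For each other list that camera called, at most 228 random lists lay as far out. The random lists were not matched on the correlation among genes, whose estimate reached 0.69 in these called lists. The counts may therefore overstate how far they stand out. The covariate of the actin control left 0 genes past the threshold by limma, against 3975 without it, and 2470 at an unadjusted p under 0.05, against 6584, and raised the median SE from 0.23 to 0.74. The count fell to 2612, 2324 and 2236 without primary replicates 2, 3 and 4, and to 1405 and 1942 without mice 3 and 4, where the 2-fold count was 1296 and 1680.

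The control probe sets separated the groups too. The actin signal dropped from the 3' to the 5' probe set by 1.49 ± 0.44 (SD, n = 4) on the log2 scale on primary arrays and by 5.33 ± 0.76 (SD, n = 4) on metastasis arrays, and Gapdh by 2.15 ± 0.48 and 5.22 ± 0.71 (SD, n = 4 each). Each difference had an exact permutation p of 0.0286 with the arrays taken as unpaired, adjusted p = 0.0371 over 13 controls, with no overlap between the groups. Bacterial hybridization controls were brighter on metastasis arrays, 11.14 ± 0.67 against 9.29 ± 0.21 (SD, n = 4 each, exact p = 0.0286). Of the bacterial poly-A transcripts added to the RNA, lys, phe and thr also dropped further from the 3' to the middle probe set on all 4 metastasis arrays (exact p = 0.0286 each), whereas dap did not differ by this test (2.07 ± 1.23 against 1.44 ± 0.43, SD, n = 4 each, exact p = 0.371). Metastasis arrays correlated with each other at 0.903 to 0.957, below the 0.981 to 0.993 of the primary arrays, across probe sets, which are not independent replicates. No label gives a batch. In primary tumours the actin and Gapdh drops of replicates 1 and 2 lay above those of replicates 3 and 4, and in metastases they lay below. Of the spike-ins, dap, phe and thr did not follow this in metastases, where they dropped less on replicates 3 and 4 than on replicates 1 and 2 (means 1.05 against 3.09, 3.38 against 4.02 and 3.42 against 4.58). The lys spike-in dropped further on replicates 3 and 4 (3.90 against 3.58), with overlap between single arrays. Medians within replicates 1 and 2 and within replicates 3 and 4 are therefore given for each list whose 2 medians had opposite signs or lay more than 0.5 apart, a cut-off chosen after seeing the data. Of these 15 lists, 9 also had both metastasis arrays 3 and 4 on one side of arrays 1 and 2, set against the primary mean. Those of the epithelial, fibroblast, B lineage, cell cycle, bone metastasis mediator and NF-kappaB lists overlapped, so there the difference is not shared by all of these arrays.

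**Figure D1:**
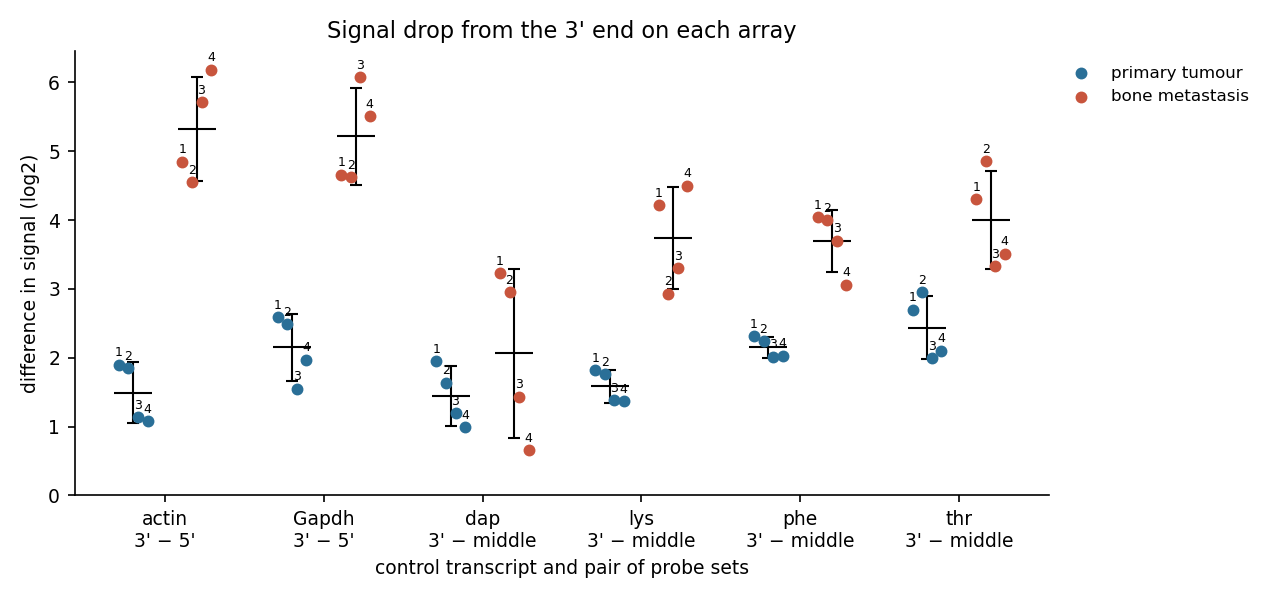
Difference in log2 signal (y axis) between the 3' and the 5' or middle probe set of 6 control transcripts (x axis) on each array, with the replicate number at each point and bars for the mean ± SD of 4 arrays. Actin and Gapdh lie at 4.55 or more on every metastasis array and at 2.59 or less on every primary array, whereas dap overlaps between the groups.

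Type I interferon response genes fell. Of 36 measured, 23 were lower, 0 were higher and 13 did not pass the test (28 lower when adjusted over the list alone), with a median log2 fold of -1.49. Ddx60, an RNA helicase of the antiviral response, changed by -2.27 (SE 0.16), Bst2, the membrane tether that holds back budding virions, by -1.70 (SE 0.14), Rtp4 by -1.97 (SE 0.21) and Ifit2, which binds viral RNA, by -3.72 (SE 0.40) on the log2 scale. All 4 fell in all 4 mice. The study followed this pathway in these samples, so neither count is independent evidence of its direction. Camera called the list lower with an adjusted p of 1.49e-13, and the call was lost with an estimated correlation (camera adjusted p = 0.0993). The list median was -1.48 in replicates 1 and 2 and -1.55 in replicates 3 and 4. Of its members, 20 were lower without metastasis replicates 1 and 3, whose keratins were low.

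Interferon gamma response genes fell as well, with 11 of 18 measured lower and 0 higher (12 lower adjusted over the list alone) and a median of -1.16. The chemokines Cxcl11, Cxcl10 and Cxcl9, which draw T cells through the receptor Cxcr3, changed by -2.27 (SE 0.25), -2.36 (SE 0.27) and -3.17 (SE 0.44), and the transcription factor Irf1 changed by -1.18 (SE 0.18). The camera adjusted p was 4.45e-07, or 0.143 with an estimated correlation. The list is again not independent evidence. The control covariate ended the call (camera adjusted p = 0.103).

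MHC class I antigen presentation genes were lower in 8 of 15 cases and higher in 0 (11 lower adjusted over the list alone), with a median of -1.67. Pdia3, a chaperone of the peptide loading complex, changed by -3.62 (SE 0.52), the immunoproteasome subunit Psmb9 by -1.81 (SE 0.31), the class I heavy chain H2-K1 by -2.50 (SE 0.43) and the proteasome activator Psme1 by -1.98 (SE 0.36). The list had a camera adjusted p of 2.06e-06, or 0.347 with an estimated correlation. These genes too lie in the pathway the study followed. The fall moved with the control drop. The median was -0.94 in replicates 1 and 2 and -2.34 in replicates 3 and 4. With the actin covariate camera called the list higher at its preset correlation, an opposite direction (adjusted p = 0.0219). The covariate is nearly tied to the group, so this direction is an extrapolation, and the list's estimated correlation was 0.69.

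Of 6 MHC class II genes, H2-Ab1, Cd74 and H2-Eb1 changed by -1.11, -1.05 and -1.35, and H2-Ob, which B cells express, rose by 3.96 (SE 0.62). The list as a whole was not called, with 3 members lower and 1 higher (4 and 1 adjusted over the list alone, median -1.02, camera adjusted p = 0.206). The median was -0.54 in replicates 1 and 2 and -1.36 in replicates 3 and 4.

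**Figure D2:**
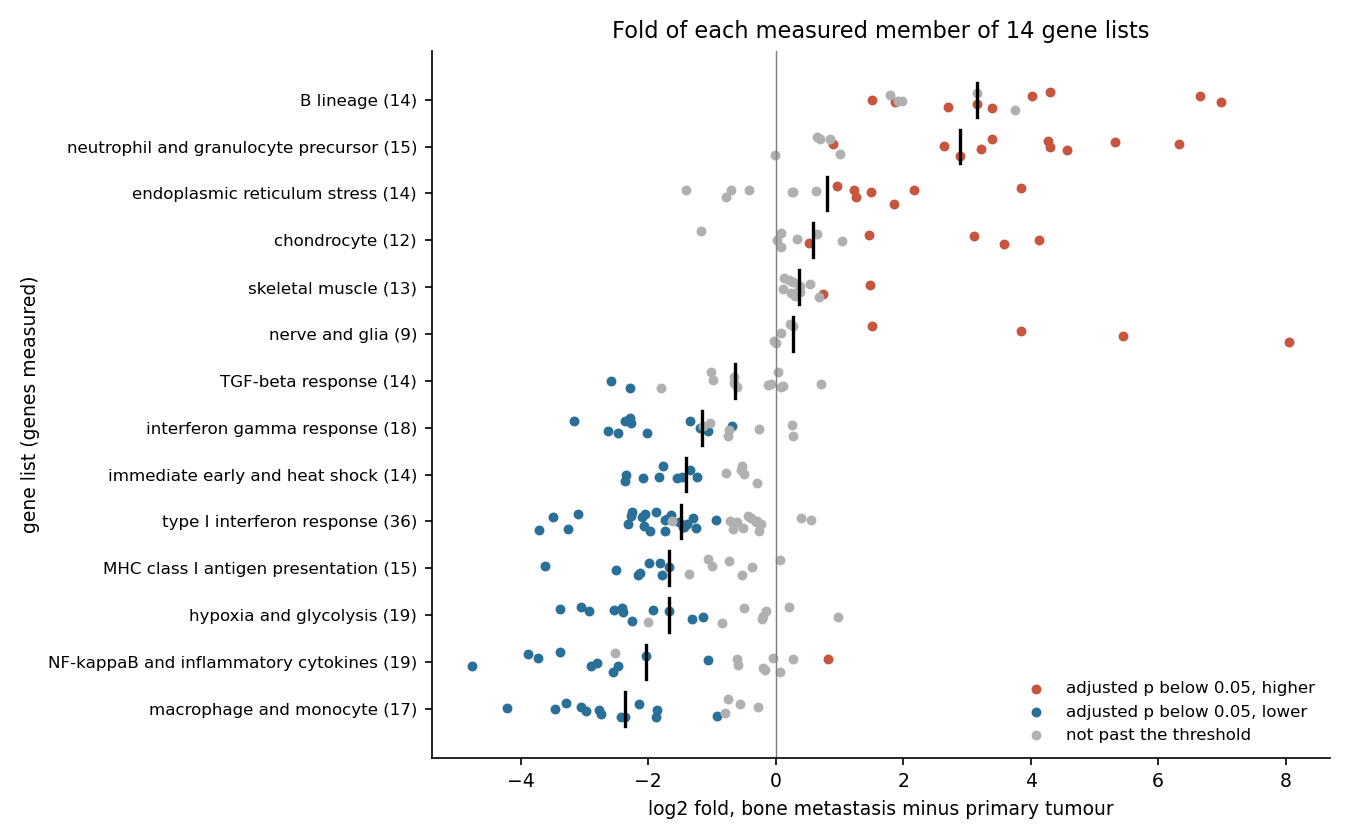
Log2 fold of bone metastasis over primary tumour (x axis) for each measured member of the 14 gene lists that camera called (y axis, with the number of genes), coloured by whether the gene passed the threshold and in which direction; black lines mark list medians. Medians run from -2.36 for macrophage and monocyte genes to 3.15 for B lineage genes.

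Macrophage and monocyte genes fell, 13 of 17 lower and 0 higher (13 adjusted over the list alone), with a median of -2.36. Adgre1, which encodes the F4/80 antigen, changed by -2.36 (SE 0.26), the complement subunits C1qc and C1qa by -3.05 (SE 0.39) and -3.29 (SE 0.43), and Aif1 by -2.74 (SE 0.42). C1qb, their partner subunit, which was looked at after these values were seen, had a fold of -0.28 (SE 0.49) on its brightest probe set and of -3.96 (SE 0.39) on another, so the size of its fold and its call rest on the probe set. Camera gave an adjusted p of 4.56e-09 for the list, or 0.232 with an estimated correlation, and 0.103 with the actin covariate. The 10 largest falls of the data set included the mannose receptor gene Mrc1 of this list, with a log2 fold of -4.21 (SE 0.70). The others were Arg1 (-5.15, SE 0.90, 35.6-fold lower), Adamdec1 (-4.83, SE 0.32), Lgmn (-4.79, SE 0.89), Ccl7 (-4.76, SE 0.24), Mmp13 (-4.71, SE 0.87), the C-type lectin gene Clec4n (-4.20, SE 0.50), Trim30d (-4.19, SE 0.28), Rab20 (-4.18, SE 0.89) and the urokinase gene Plau (-4.17, SE 0.51), each lower in all 4 mice. With the actin covariate the folds of Lgmn, Mmp13, Mrc1 and Rab20 turned positive, with 0 genes past the threshold by limma. The covariate is nearly tied to the group and raised the median SE over all genes from 0.23 to 0.74.

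NF-kappaB targets and inflammatory cytokines fell in 10 of 19 cases and 1 rose (12 lower and 1 higher adjusted over the list alone), with a median of -2.04. The monocyte chemoattractants Ccl7 and Ccl2 changed by -4.76 (SE 0.24) and -3.73 (SE 0.40), the neutrophil chemoattractant Cxcl5 by -3.38 (SE 0.48) and Tnf by -2.80 (SE 0.44). For the list the camera adjusted p was 4.64e-05, or 0.365 with an estimated correlation. The median was -0.78 in replicates 1 and 2 and -2.61 in replicates 3 and 4, but -2.02, -0.36, -1.80 and -2.85 on metastasis arrays 1 to 4 against the primary mean, so that array 2 stood apart. With the actin covariate the direction of the list turned without a call (camera adjusted p = 0.828). Immediate early and heat shock genes were lower in 9 of 14 cases and higher in 0 (11 lower adjusted over the list alone), with a median of -1.41. Among them Atf3 changed by -2.37 (SE 0.25), Zfp36, which destabilises cytokine mRNA, by -2.35 (SE 0.32), Fosb by -1.77 (SE 0.30) and Btg2 by -1.34 (SE 0.23). The camera adjusted p was 4.45e-07, or 0.232 with an estimated correlation and 0.986 with the actin covariate. In replicates 1 and 2 their median was -1.02, and in replicates 3 and 4 it was -1.77.

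Hypoxia and glycolysis genes fell in 11 of 19 cases and rose in 0 (14 lower adjusted over the list alone), with a median of -1.68. Car9, a carbonic anhydrase induced by hypoxia, changed by -2.93 (SE 0.21, limma adjusted p = 0.000211), the collagen prolyl hydroxylase subunit P4ha1 by -3.38 (SE 0.30), and the glycolytic enzymes Tpi1 and Ldha by -1.92 (SE 0.14) and -1.68 (SE 0.19). By camera the list had an adjusted p of 9.89e-08, or 0.143 with an estimated correlation and 0.434 with the actin covariate. Its median was -1.41 in replicates 1 and 2 and -1.94 in replicates 3 and 4. Oxidative phosphorylation genes split, 6 higher and 3 lower of 20 (7 and 6 adjusted over the list alone). Ndufa1 and Cox7a2, subunits of complexes of the respiratory chain, rose by 0.92 (SE 0.13) and 0.98 (SE 0.17), and Ndufv1 and Uqcrc2 rose by 0.87 and 0.94 but lay at -1.30 and -0.79 with the most variable probe set. The list was not called (camera adjusted p = 0.753, toward higher, with a median of -0.01 and a mean of -0.17), and its median turned from 0.29 in replicates 1 and 2 to -0.33 in replicates 3 and 4.

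Endoplasmic reticulum stress genes went the other way, 7 of 14 higher and 0 lower (7 higher and 2 lower adjusted over the list alone), with a median of 0.80. Chac1, which degrades glutathione, rose by 3.84 (SE 0.27, limma adjusted p = 0.000191), the asparagine synthetase Asns by 1.86 (SE 0.24), Ddit3, which encodes CHOP, by 1.49 (SE 0.20) and Atf4 by 1.27 (SE 0.20), each in all 4 mice. Other probe sets of Asns and Atf4 gave -0.02 (SE 0.34) and -0.68 (SE 0.23), so the rises of these genes rest on the probe set. Of the 7 members not called, Hsp90b1 and Hspa5 had other probe sets with a call, 1 of these genes lower only and 1 both ways. Camera called the list higher with an adjusted p of 0.0233, or 0.413 with an estimated correlation. The call was lost without metastasis replicate 2 (camera adjusted p = 0.117), without mouse 2 (0.100) and with the mean or the most variable of a gene's probe sets (0.159 and 0.168).

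**Figure D3:**
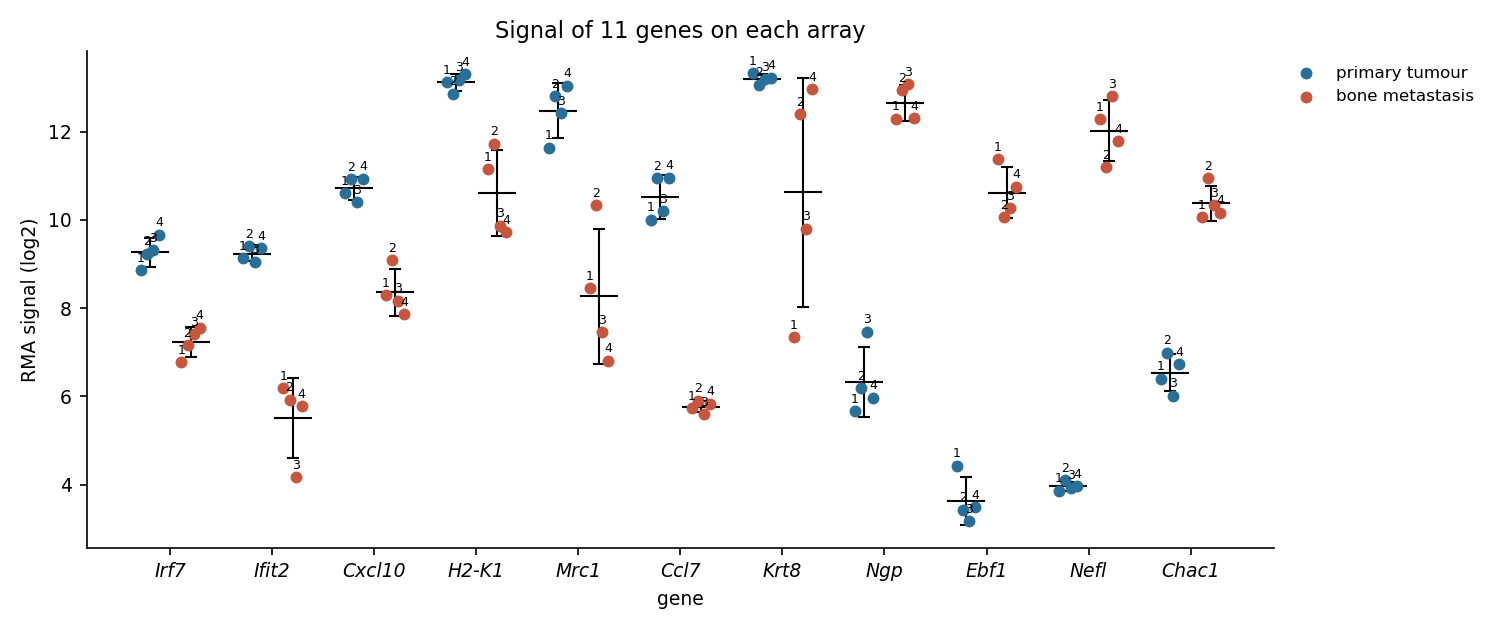
Log2 RMA signal (y axis) of 11 genes (x axis) on each array, with the replicate number at each point and bars for the mean ± SD of 4 arrays; Krt8 was chosen after its values were seen. Irf7, Ifit2 and Ccl7 lie lower on every metastasis array than on every primary array, Ngp, Ebf1, Nefl and Chac1 lie higher, and Krt8 ranges from 7.34 to 12.97 over the metastasis arrays.

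Neutrophil and granulocyte precursor genes rose, 10 of 15 higher and 0 lower (13 higher adjusted over the list alone), with a median of 2.90. The granule proteins Ngp and Camp rose by 6.33 (SE 0.39, 80.3-fold) and 4.28 (SE 0.25), the calgranulin S100a9 by 5.33 (SE 0.38) and the myeloperoxidase gene Mpo by 3.40 (SE 0.28). Camera gave an adjusted p of 1.16e-08, or 0.112 with an estimated correlation. B lineage genes rose in 9 of 14 cases and fell in 0 (12 higher adjusted over the list alone), with a median of 3.15. Ebf1, a transcription factor that commits progenitors to the B lineage, rose by 6.98 (SE 0.35), the surrogate light chain gene Vpreb1 by 6.66 (SE 1.26), Ms4a1 by 4.03 (SE 0.37), Cd79a by 3.39 (SE 0.47) and Cd79b by 4.31 (SE 0.66). Camera gave an adjusted p of 4.01e-07, or 0.232 with an estimated correlation. The B lineage median was 4.14 in replicates 1 and 2 and 2.14 in replicates 3 and 4. On single metastasis arrays it lay 1.54 to 4.98 above the primary mean. Neither marrow list lost its camera call with the actin covariate.

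The 10 largest rises included nerve genes. In 8 of the 10 the primary mean lay between 3.40 and 4.93, under the array median of 5.16, so their log2 folds and their order are not exact. Nefl and Nefm, neurofilament subunits of large axons, rose by 8.05 (SE 0.31, limma adjusted p = 3.45e-05) and 5.45 (SE 0.51). Snap25 and Syt1, of the synaptic vesicle machinery, rose by 3.86 (SE 0.73) and 1.51 (SE 0.27). Outside the list, Stmn3, Pirt, Mapk10 and Elavl2 rose by 6.41 (SE 0.41), 6.17 (SE 0.50), 6.15 (SE 0.56) and 6.0 (SE 0.41). Of 9 nerve and glia genes, 4 were higher and 0 lower (4 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.00663, or 0.143 with an estimated correlation and 0.0905 with the actin covariate). Mbp and Mobp, genes of myelin looked at after their values were seen, count as not called here at 0.08 (SE 0.28) and 0.27 (SE 0.22), but 4 other Mbp probe sets lay at 6.43 to 7.84 and 1 of Mobp at 3.84, so count and median rest on the probe set. Fmod, a small proteoglycan of tendon and cartilage, and Prg4, the joint lubricant, rose by 6.89 (SE 0.82) and 6.39 (SE 0.47). Of 12 chondrocyte genes 5 were higher and 0 lower (6 higher adjusted over the list alone), with a median of 0.59. Comp rose by 4.13 (SE 0.40), Chad by 3.59 (SE 0.61), Acan by 3.12 (SE 0.73) and Col2a1, at low signal, by 1.47 (SE 0.32). Sox9, the transcription factor of cartilage formation, looked at after its values were seen, had a fold of -1.18 (SE 0.49) that did not pass (limma adjusted p = 0.122), and its other probe sets gave -2.56 (SE 0.33) and -0.39 (SE 0.16). Camera gave the chondrocyte list an adjusted p of 0.0158, or 0.347 with an estimated correlation, and its direction turned with the actin covariate (0.586). Its median was 0.33 in replicates 1 and 2 and 0.96 in replicates 3 and 4.

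Skeletal muscle genes had a median of 0.37 with 2 of 13 higher, Pvalb by 1.48 (SE 0.24) and Tnnt3 by 0.75 (SE 0.16), and 0 lower (2 adjusted over the list alone). Their camera adjusted p of 0.0158 became 0.413 with an estimated correlation. The call was lost with quantile normalization (0.114), cyclic loess (0.0940) and the filter at the median (0.0535), and the direction turned with the actin covariate (0.213). TGF-beta response genes had a median of -0.63 with 2 of 14 lower, Thbs1 at -2.58 (SE 0.70) and Tgfbr1 at -2.29 (SE 0.68), but 0 adjusted over the list alone, and 0 higher. Their camera adjusted p of 0.0333 became 0.232 with an estimated correlation. The call was lost under most changes of scaling or filter and without metastasis replicate 1 or 4 (0.0584 and 0.0838) or mouse 1 or 4 (0.0669 and 0.0845).

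Epithelial genes, the markers of the tumour cells, were mostly not called: of 28, 3 were lower and 1 higher (the same counts adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.0549, or 0.0330 with the mouse as a block). Their median was -0.59 in replicates 1 and 2 and -0.00 in replicates 3 and 4. Of the 24 members not called, 4 had another probe set called lower and 1 had one called higher (Cldn3, Dsp, Epcam, Esrp2 and Spint2 together). The count of calls thus rests on the probe set. Krt19 changed by -3.36 (SE 0.64), Cldn4 by -1.55 (SE 0.34) and Spint1 by -1.44 (SE 0.35, limma adjusted p = 0.0206, or 0.0647 with the mouse as a block), and Tjp3, at low signal, rose by 0.82 (SE 0.12). Krt8, looked at after its values were seen, had a log2 signal of 13.20 ± 0.11 (SD, n = 4) on primary arrays and of 7.34, 12.39, 9.80 and 12.97 on metastasis arrays 1 to 4, a fold of -2.57 (SE 1.09) that did not pass the test (limma adjusted p = 0.126). Krt18 showed the like, with 6.05, 10.95, 8.49 and 11.86 on the metastasis arrays against 11.60 ± 0.25 (SD, n = 4). Without metastasis replicates 1 and 3, an alternative chosen after seeing these keratins, the lists that camera called changed as follows. Type I interferon, interferon gamma, MHC class I, macrophage and hypoxia genes were lower in 20, 10, 8, 9 and 9 cases, and NF-kappaB, immediate early and TGF-beta genes in 5, 5 and 0, against 10, 9 and 2 on all arrays. The medians of the NF-kappaB, immediate early and TGF-beta lists were then -1.93, -1.21 and -0.42, against -2.04, -1.41 and -0.63. The lost calls of the NF-kappaB and immediate early lists thus came with falls of nearly the same size. Neutrophil, B lineage and endoplasmic reticulum stress genes were higher in 10, 9 and 7 cases, and chondrocyte, nerve and muscle genes in 4, 3 and 2. Mammary secretory and hormone-responsive genes had 1 of 9 lower, the casein gene Csn3 with a fold of -3.88 (SE 0.74), and 0 higher (1 adjusted over the list alone, median -0.45, camera adjusted p = 0.222). Csn2 had a fold of -3.90 (SE 1.24, limma adjusted p = 0.0545, or 0.0471 with the mouse as a block).

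Of 19 genes known as mediators of bone metastasis, 5 were lower and 2 higher (7 and 2 adjusted over the list alone), with a median of -0.81, and the list was not called (camera adjusted p = 0.116). Its median was -1.05 in replicates 1 and 2 and -0.37 in replicates 3 and 4. Vcam1, Mmp13 and Ptgs2 changed by -4.05 (SE 0.70), -4.71 (SE 0.87) and -3.88 (SE 0.76), and the chemokine receptor Cxcr4 rose by 1.41 (SE 0.20). Mesenchymal transition genes had 2 lower and 1 higher of 11 (4 lower and 1 higher adjusted over the list alone, median -0.23, camera adjusted p = 0.222), and their median turned from -0.39 in replicates 1 and 2 to 0.08 in replicates 3 and 4. Vim changed by -1.48 (SE 0.23), though its probe set brightest in metastasis gave 0.07. Twist1 changed by -1.92 (SE 0.58, limma adjusted p = 0.0466, or 0.0753 with the mouse as a block) and Zeb1 rose by 2.01 (SE 0.59). Foxc2 had a fold of -1.21 (SE 0.38) that did not pass the test (limma adjusted p = 0.0508). Of 24 cell cycle genes, 5 were lower and 0 higher (7 lower adjusted over the list alone, median -0.35, camera adjusted p = 0.116), among them Bub1 at -1.94 (SE 0.42), Plk1 at -0.70 (SE 0.20), Cdk1 at -1.52 (SE 0.41) and Aurka at -0.80 (SE 0.22). Of the 19 members not called, 4 had another probe set called higher and 2 had one called lower (Cdc20, Kif11, Mcm3, Mcm7, Top2a and Tyms together). The cell cycle counts thus rest on the probe set. With the mouse as a block Cdk1 and Aurka no longer passed (limma adjusted p = 0.0548 and 0.0747, against 0.0297 and 0.0333 without it). The cell cycle median was 0.21 in replicates 1 and 2 and -0.73 in replicates 3 and 4, but 0.82, -0.63, -1.12 and -0.44 on metastasis arrays 1 to 4 against the primary mean. Array 1 alone lay above it, and without that array camera called the list lower (adjusted p = 0.000707, or 0.00416 without mouse 1). These calls rest on the preset correlation. On all arrays the list's estimated correlation was 0.76, and camera's adjusted p with it was 0.739.

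Markers of other cells of bone mostly did not separate the groups as lists. Osteoblast and osteocyte genes had 1 of 11 higher, Ibsp, the bone sialoprotein gene, by 2.74 (SE 0.42), and 0 lower (1 adjusted over the list alone, median 0.24, camera adjusted p = 0.0503, or 0.0466 with the mouse as a block). Alpl had a fold of 0.58 (SE 0.18) that did not pass (limma adjusted p = 0.0529). Osteoclast genes had 3 of 14 lower and 1 higher (the same adjusted over the list alone, median -0.51, camera adjusted p = 0.0621). Acp5, Ocstamp and Tcirg1 changed by -2.89, -2.15 and -1.91, and Itgb3 rose by 1.44. Fibroblast and matrix genes had 3 of 24 higher and 2 lower (the same adjusted over the list alone, median 0.02, camera adjusted p = 0.968), and their median turned from -0.17 in replicates 1 and 2 to 0.27 in replicates 3 and 4. Dcn and Thy1 rose by 2.51 (SE 0.35) and 3.82 (SE 0.66), and Fn1 had a fold of -1.77 (SE 0.36). Pdgfra had a fold of -2.15 (SE 0.51), lower in 3 of 4 mice, that passed without the mouse block only (limma adjusted p = 0.0184, or 0.0591 with it). T and natural killer cell genes had 2 of 17 higher, Gzma by 2.19 (SE 0.27) and Klrd1 by 2.08 (SE 0.36), and 0 lower (2 adjusted over the list alone, median 0.26, camera adjusted p = 0.250), with medians of 0.00 in replicates 1 and 2 and 0.52 in replicates 3 and 4. Endothelial genes had 2 of 14 higher, Cldn5 by 1.84 (SE 0.36) and Plvap by 1.55 (SE 0.35), and 0 lower (2 adjusted over the list alone, median 0.24, camera adjusted p = 0.319). None of 11 erythroid, 8 megakaryocyte and platelet or 9 adipocyte genes passed the test by limma in either direction, also when adjusted over the list alone (medians 0.31, 0.32 and 0.30, camera adjusted p = 0.119, 0.581 and 0.159). The erythroid median was -0.01 in replicates 1 and 2 and 0.53 in replicates 3 and 4. Their members named by the rule had folds of 0.47 (Slc4a1), 0.44 (Ermap), 0.31 (Gp1bb), 1.04 (Lpl) and 0.54 (Retn). Another probe set of Gp1bb was called higher, so its missing call rests on the probe set. The camera direction and median of the megakaryocyte list were toward higher while its mean was -0.03, and Pf4 had a fold of -1.25 (SE 0.45, limma adjusted p = 0.0819, or 0.0317 with the mouse as a block).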

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

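In this part, all weighing tests except the count of sensory neuron genes and the splits of the arrays were chosen after the result they measure had been seen. Within groups of 4 arrays, 15 of 318 sets of values had 1 array far from the other 3 relative to the group's range, and chance gives about 15.9. The 15 values are these. Among metastasis arrays, Fmod had a log2 signal of 8.37 on replicate 2 against 11.92 to 12.21 on the others, Clec4n 9.42 on replicate 2 against 7.06 to 7.43, Vim 12.87 on replicate 2 against 11.91 to 12.06, and Fosb 10.49 on replicate 2 against 9.07 to 9.27. On the same array the neutrophil list's median lay 3.71 above the primary mean, against 2.42 to 2.55 on the others. S100a9 had 11.75 on replicate 1 against 13.08 to 13.20, Cldn5 7.66 on replicate 1 against 8.87 to 9.11, Lpl 9.84 on replicate 3 against 8.87 to 8.96, and Tnnt3 5.16 on replicate 4 against 4.61 to 4.68. Among primary arrays, Rab20 had 8.58 on replicate 1 against 10.12 to 10.41, Csn3 8.24 on replicate 1 against 9.93 to 10.08, Vcam1 12.11 on replicate 1 against 12.86 to 13.00, Tjp3 4.92 on replicate 2 against 4.87 to 4.88, Col2a1 5.04 on replicate 2 against 4.81 to 4.85, and Cd79b 4.99 on replicate 2 against 5.73 to 5.87.

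For the fall of type I interferon genes, a 3' bias acting alike on genes of the same brightness is argued against, since the list's median of -1.49 lay below the 95% range of 10000 matched random lists (-0.79 to 0.02), none of which was as low (a test added once its own result and the inconclusive result of the next were known). The random lists leave out the correlation among the list's genes, estimated at 0.08, so their range may be too narrow. A bias acting by where each probe set lies in its transcript stays open, since the metastasis arrays with the larger actin and Gapdh drop (3 and 4) differed from the other 2 by 0.17 (interval -0.27 to 0.44). With the actin covariate camera still called the list (adjusted p = 0.000105), but Irf7 went from -2.04 (SE 0.23) to -2.48 (SE 0.87), its call ending because the SE rose. As far as Krt8 gauges them, a loss of tumour cells as the whole cause is argued against. On the 2 metastasis arrays with Krt8 within 1 log2 unit of the primary mean (2 and 4), the interferon list still lay at -1.17 (interval -1.56 to -0.81). The epithelial list's median lay at -0.17 and 0.14 on these arrays. Krt19 (5.06 and 5.57 against a primary mean of 8.06), Cldn4 and Spint1 lay lower there, however, so an unchanged share of tumour cells was not shown. Fewer macrophages could be a cause and cannot be told apart from a change within tumour cells, since the interferon list's median minus the macrophage list's was 0.87 with an interval of -0.53 to 1.61. The tissue itself, bone against mammary gland, stays open and untested.

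Of marrow, cartilage and nerve lists, 10 of 15 neutrophil, 9 of 14 B lineage, 5 of 12 chondrocyte and 4 of 9 nerve and glia genes were higher in bone metastasis. Their camera calls were lost with an estimated correlation (adjusted p = 0.112, 0.232, 0.347 and 0.143), and with the actin covariate the nerve call was lost and the chondrocyte direction turned. A normalization that lifts all dim genes is argued against for the B lineage and neutrophil lists. Genes dimmer than the array median in primary tumours had a median fold of 0.20 (quartiles 0.07 and 0.37), while these lists had 3.15 and 2.90. For the chondrocyte and nerve lists as wholes it stays open, since their medians were 0.59 and 0.27. It is argued against for the sensory neuron list named below, whose 15 measured genes had a median of 3.39. RNA from other cells of the spine is a candidate explanation. Its test was written before its own genes were looked at, but after other nerve genes had been seen to rise. Of the sensory neuron list, 100% of measured genes were called higher, against 9.72% of all genes. Genes that share a cell type are not independent of one another (camera p = 0.0651 with an estimated correlation), so this count is not independent of the earlier rises. The labels name an isolation of tumour epithelial cells that would remove other cells of the spine, without giving its method. Expression of the marrow, cartilage and nerve genes by tumour cells in bone was not excluded.

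The 3' to 5' signal drop was larger on metastasis arrays. The labelling reaction may contribute, since 3 of 4 bacterial spike-in transcripts, which do not pass through the tissue, dropped further on every metastasis array than on every primary array. As the whole cause of the differences among metastasis arrays it is argued against by 3 of the 4 spike-ins. Actin and Gapdh dropped further on arrays 3 and 4 than on 1 and 2 (by 0.86 and 1.08 from the 3' to the middle probe set), while dap, phe and thr differed by -2.05, -0.64 and -1.16. The lys spike-in differed by 0.32, the same way as actin and Gapdh. Degraded tissue RNA cannot be told apart from the labelling reaction, since the excess of actin and Gapdh from the 3' to the middle probe set was 1.92 and those of the spike-ins ran from 0.63 to 2.15. Both group and drop separate the arrays in the same way, so the design leaves open how far the drop enters any gene's fold.

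Splits of the 8 arrays into 4 and 4 bear on chance. For the 3975 genes past the threshold and for the 2897 that also differed 2-fold, 1 of the 35 splits, the real one, gave as many. The highest of the others was 0 in both cases. With the arrays taken as unpaired this argues against chance, at the smallest share that 35 splits allow. The other splits mix the groups, so a group difference of any cause widens the spread within their parts, and their counts of 0 add little. The arrays are paired by mouse, though, and the 8 splits that part all 4 pairs are too few for a share under 0.05: 1 of 8 gave as many, and the highest other was again 0. For the number of gene lists past the threshold chance cannot be excluded: the real split called 14, the highest other called 17, and 7 of 35 splits called as many. Among the 8 splits that part all pairs, 3 did so, with a highest other of 16. The splits other than the real one called lists while calling 0 genes.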

How the results depend on the processing

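In this part, leaving out metastasis replicates 1 and 3, the actin covariate, the probe set brightest in metastasis and the block of replicates 1 and 2 against 3 and 4 were chosen after seeing the data. Camera's calls on the type I interferon, neutrophil and B lineage lists kept their direction and side of the threshold under every alternative run with camera (the mouse as a random block was not) except the estimated correlation, and those on the interferon gamma, macrophage, hypoxia, immediate early and nerve lists also lost theirs with the actin covariate. The calls on the MHC class I, NF-kappaB and chondrocyte lists turned direction with it. Leaving out 1 array or 1 mouse in turn gave 1405 to 4813 genes past the threshold (1405 without mouse 3, 1942 without mouse 4, and 2612, 2324 and 2236 without primary replicates 2, 3 and 4), 1296 to 3542 at 2-fold, 50.4% to 60.7% of calls lower, and Irf7 from -2.18 to -1.89. The camera adjusted p then ranged from 0.00576 to 0.233 for epithelial genes, 0.147 to 0.983 for fibroblast genes (direction turned), 0.0171 to 0.143 for osteoblast genes, 0.0280 to 0.150 for osteoclast genes, 0.0366 to 0.483 for T and natural killer cell genes, 0.000707 to 0.553 for cell cycle genes, 0.0481 to 0.298 for bone metastasis mediators, 0.00682 to 0.0845 for TGF-beta genes, 0.00817 to 0.117 for endoplasmic reticulum stress genes and 0.353 to 0.973 for oxidative phosphorylation genes (direction turned). Fewer arrays explain part of the lost calls. For all other changes in this part the cause was not tested. What is limited by signal over background could not be set array by array, since no background values were used, and the filters on dim genes stand in for it.

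With the mouse as a block, 57.7% of calls were lower, and the epithelial and osteoblast lists passed the threshold (camera adjusted p = 0.0330 and 0.0466). The pairing changed no other list's call and not that of Irf7, and of the genes named by the rule it ended the calls of Spint1, Twist1, Pdgfra, Cdk1 and Aurka and added those of Csn2 and Pf4. Across scalings and filters, the share of calls lower was 61.3% with the filter at the median, 66.8% with the filter at the 75th percentile, 49.2% with quantile normalization, 44.4% with 75th percentile scaling, 51.3% with cyclic loess, 53.6% with array weights, 59.0% with the mean over probe sets, 60.5% with the most variable probe set, 51.4% with the probe set brightest in metastasis, 57.2% with replicates 1 and 2 against 3 and 4 as a block and 52.7% without metastasis replicates 1 and 3. Testing every probe set gave 8201 calls. With the filter at the median the camera adjusted p was 0.0535 for muscle and 0.135 for TGF-beta genes. With the filter at the 75th percentile it was 0.0209 for endothelial, 0.564 for cell cycle (direction turned) and 0.325 for TGF-beta genes. Quantile normalization gave 0.114 for muscle and 0.186 for TGF-beta genes, and cyclic loess 0.0940 and 0.230. Scaling to the 75th percentile gave 0.971 for fibroblast (turned) and 0.0353 for osteoblast genes. A trended variance gave 0.0432 for epithelial and 0.0400 for osteoblast genes. Array weights gave 0.0461 for epithelial and 0.0388 for osteoblast genes, and the block of replicates 1 and 2 against 3 and 4 gave 0.0400 for osteoblast genes. The mean over probe sets gave 0.0350 for epithelial, 0.841 for fibroblast (turned), 0.0210 for osteoblast, 0.0272 for cell cycle, 0.159 for endoplasmic reticulum stress and 0.200 for oxidative phosphorylation genes (turned). The most variable probe set gave 0.938 for fibroblast (turned), 0.0499 for osteoblast, 0.00756 for cell cycle, 0.168 for endoplasmic reticulum stress and 0.117 for oxidative phosphorylation genes (turned), and it turned Ndufv1 to -1.30 and Uqcrc2 to -0.79. The probe set brightest in metastasis gave 0.0470 for osteoclast and 0.400 for TGF-beta genes and turned Vim to 0.067. Without metastasis replicates 1 and 3 it was 0.548 for fibroblast (turned), 0.0167 for osteoblast, 0.00637 for cell cycle, 0.0904 for TGF-beta and 0.565 for oxidative phosphorylation genes (turned). Fry, which asks whether a list's genes changed on balance and does not compare them with other genes, gave an adjusted p of 0.00321 for osteoblast and 0.0128 for osteoclast genes. These values answer another question than camera's and do not support a difference from other genes.

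With an estimated correlation the camera adjusted p was 0.0993 for type I interferon, 0.143 for interferon gamma, hypoxia and nerve, 0.347 for MHC class I and chondrocyte, 0.112 for neutrophil, 0.232 for B lineage, macrophage, TGF-beta and immediate early, 0.413 for muscle and endoplasmic reticulum stress, and 0.365 for NF-kappaB genes. The actin covariate, which is nearly tied to the group, left 0 genes past the threshold and 0 at 2-fold by limma, against 3975 and 2897 without it, and 2470 at an unadjusted p under 0.05, against 6584. Irf7 was at -2.48 under it. It turned Lgmn to 1.88, Mmp13 to 3.02, Mrc1 to 1.94, Rab20 to 2.01, Pdia3 to 1.41, H2-K1 to 1.42, H2-Ab1 to 0.48, H2-Eb1 to 0.94, Vim to 0.0019, Fn1 to 0.23, Tcirg1 to 0.94, Csn3 to 0.21, Cdk1 to 0.71, Aurka to 0.36, Ptgs2 to 1.86, Tgfbr1 to 3.53, Zfp36 to 0.16 and Btg2 to 0.10, and Thy1 to -0.16, Ermap to -0.16, Gp1bb to -0.47, Retn to -0.58 and Tnnt3 to -0.081. Its camera adjusted p was 0.103 for interferon gamma and macrophage, 0.0905 for nerve, 0.434 for hypoxia and 0.986 for TGF-beta and immediate early genes, all in the same direction as without it, and 0.000605 for epithelial and 2.43e-05 for oxidative phosphorylation genes, which then passed. The direction turned for MHC class I (0.0219), MHC class II and T and natural killer cell (0.344 each), fibroblast (0.579), chondrocyte (0.586), erythroid (0.0878), megakaryocyte (0.0905), endothelial (0.593), muscle (0.213), cell cycle (0.103), bone metastasis mediators (0.853) and NF-kappaB genes (0.828).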

Other observations

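In this part the lists and the comparisons among metastasis arrays were chosen after a first look at the data. The sensory neuron list was written before the values of its genes were seen, but after other nerve genes had been seen to rise. Scn9a, Rbfox3, Cntnap2 and Chgb, looked at after their values were seen, rose by 4.59, 5.81, 4.97 and 4.87. None of the measured genes of the lists in this part is in a list fixed earlier. Genes of sensory neurons, which lie in the dorsal root ganglia beside the vertebrae, were higher in bone metastasis. All 15 measured of 20 passed the threshold upward in limma, each in 4 of 4 mice, with a median log2 fold of 3.39. Pou4f1, a transcription factor of sensory ganglia, rose from 4.47 to 8.40 (SE 0.61), Tac1, which encodes substance P, from 5.61 to 9.49 (SE 0.78), the intermediate filament gene Prph from 5.45 to 8.84 (SE 0.42), Avil from 6.30 to 9.60 (SE 0.49), the nociceptor sodium channel gene Scn11a from 4.59 to 8.30 (SE 0.82) and Ret from 4.05 to 7.54 (SE 0.52). Primary signals under the array median of 5.16, as for Pou4f1, Scn11a and Ret, make such rises inexact. Camera gave a p of 5.76e-10 for the list, or 0.0651 with an estimated correlation. Of 13 central neuron and glia genes 1 was higher, Neurod2 by 0.42. That list's median was 0.15 and its camera p 0.220, or 0.647 with an estimated correlation. Of 12 Schwann cell and satellite glia genes 4 were higher, S100b, L1cam, Ngfr and Cdh19, and 1 lower, Egr2. Their median was 0.96 and the list's camera p 0.0222, or 0.147 with an estimated correlation.

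Tendon and synovium genes parted. Of 12 measured, 6 were higher and 0 lower, with a median of 0.46 (camera p = 0.000321, or 0.0411 with an estimated correlation), but Fmod and Prg4 had been seen to rise when the list was written. Without these, 4 of 10 were higher and 0 lower, with a median of 0.26 (camera p = 0.00945, or 0.0767 with an estimated correlation). Cilp rose by 3.33 (SE 0.58), Ecrg4 by 3.60 (SE 0.68), Thbs4 by 2.66 (SE 0.22) and Angptl7 by 0.60 (SE 0.17). The tendon transcription factors Scx and Mkx had folds of -0.03 and -0.03, and Tnmd, a marker of mature tendon cells, 0.17, none past the threshold at signals near 4.

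Of the 29 lists, 12 differed among the metastasis arrays themselves with an interval off 0, 6 lower and 6 higher on replicates 3 and 4 than on replicates 1 and 2. On replicates 3 and 4 the drop of actin and Gapdh was larger, that of the spike-ins dap, phe and thr smaller, and that of lys larger by 0.32. The mean signal of 5' probe sets of actin and Gapdh differed by -1.22. MHC class I genes differed by a median of -1.05 (interval -1.87 to -0.97), MHC class II genes by -0.84 (-1.44 to -0.13), cell cycle genes by -0.96 (-1.16 to -0.84), B lineage genes by -1.90 (-2.50 to -0.60), oxidative phosphorylation genes by -0.63 (-0.93 to -0.30) and endoplasmic reticulum stress genes by -0.28 (-0.70 to -0.06), against 0.09 over all genes. Chondrocyte genes differed by 0.63 (0.14 to 0.93), megakaryocyte genes by 0.57 (0.39 to 0.81), erythroid genes by 0.42 (0.21 to 0.78), epithelial genes by 0.38 (0.15 to 0.60), endothelial genes by 0.31 (0.11 to 0.54) and muscle genes by 0.30 (0.18 to 0.48). Type I interferon genes, whose interval spans 0, differed by 0.17 (-0.27 to 0.44). The cell cycle difference comes mostly from replicate 1, at 0.82 above the primary mean, since replicate 2 at -0.63 lay below replicate 4 at -0.44. That of endoplasmic reticulum stress genes comes from replicate 2, at 1.44, since replicate 1 at 0.61 lay below replicates 3 and 4 at 0.81 and 0.84. The B lineage and epithelial arrays overlapped too. These intervals come from resampling genes and leave out the spread between arrays.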
